A study of Mus musculus with 2 samples.

How the data were processed

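MicroRNA-seq was performed on adrenal glands of 10-day-old female mice of strain B6CASTF1/J, the first-generation offspring of a cross between C57BL/6J and CAST/EiJ mice. The 2 libraries form 1 group. They are labelled biological replicates 1 and 2, each with 1 technical replicate, and the labels number the animals 3 and 4. Both samples also carry the same donor entry in the labels, so their standing as separate animals rests on the replicate and animal numbers. The labels give a small-RNA size range and name a multiplexed library protocol. No paper was used.

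The deposited values are raw read counts per microRNA gene, made by the authors from each library separately. The genome build is mm10 (GRCm38) and the gene annotation is GENCODE M21, per the text deposited with each library. The aligner, the counting program and their versions are not given in the sources used here. Each table holds 3 columns of counts, which by their values are reads irrespective of strand, reads on the strand of the gene and reads on the opposite strand. The 4 summary lines at the head of each table show that reads with several alignments, reads outside microRNA genes and reads overlapping more than 1 gene were not counted. These summary lines stayed out of library totals and tests. In replicates 1 and 2, reads with several alignments made up 25.0% and 27.2% of all reads, unmapped reads 28.1% and 26.4%, and reads outside microRNA genes 8.55% and 8.86%. No read was ambiguous in the strand-specific count.

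The reads on the strand of the gene were the main measurement. In the column counted irrespective of strand, 621695 and 667292 reads were ambiguous, because some microRNA genes overlap another annotated microRNA gene on the opposite strand. All 2202 gene identifiers were matched to the M21 annotation, which gave symbols, coordinates, host genes and hairpin sequences. Counts are per hairpin gene, so the mature products of the 5' and 3' arms were not separated. Reads that fit near-identical gene copies equally well are missing from these counts, and values of genes with a numbered copy, such as Mir24-1 and Mir24-2, are therefore uncertain.

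CPM, the count of a gene scaled to a fixed library total, was computed over all counts assigned to microRNA genes. A gene was called detected at 10 CPM or more in both animals. Means are given with the SD over the 2 animals. Shares of counts in a single library have exact Clopper-Pearson 95% intervals. A count of 0 allows up to 3 counts, which is 1.48 CPM in replicate 1 and 0.935 CPM in replicate 2. The protocol sources used here name no molecular identifiers, so these intervals and limits cover counting error only.

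The 2 libraries were compared gene by gene over the 329 genes with at least 10 CPM in either animal. A gene that reached this floor in a single animal was higher there by construction. The test was a two-sided exact conditional binomial test on the counts with TMM-scaled library sizes from edgeR 4.0.16, with Benjamini-Hochberg adjustment at 0.05. It compares these 2 libraries, not conditions. Log2 ratios are replicate 2 over replicate 1, on TMM-scaled CPM with a pseudocount of 1 CPM, which understates the differences of low genes. Intervals of log2 ratios are exact 95% intervals without the pseudocount. A chi-square statistic of 510404.6 on 437 degrees of freedom showed that the libraries were not 1 library deposited again. The biological coefficient of variation was the square root of edgeR's common dispersion with an intercept-only design, with an interval from 100 bootstrap draws of genes. Calculations ran in R 4.3.3 and in Python 3.11.15 with SciPy 1.17.1 and pandas 2.3.3.

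The grouping, the tests, 25 gene lists, the alternative settings and the rule for named genes were fixed before the data were examined. The lists covered families (let-7, miR-17/92 and its paralogs, miR-30, miR-29, miR-23/27/24, the Hox-cluster microRNAs, the Sfmbt2 family), imprinted regions (Dlk1-Dio3, Igf2 and H19), microRNAs tied to adrenal steroid synthesis, and cell types or tissues. The latter were neuroendocrine cells, neurons, endothelium, smooth muscle and stroma, epithelium, red blood cells, leukocytes, striated muscle, liver, kidney or gut epithelium, brown fat, pancreas, pluripotent cells, testis and Mir202 of the gonads. Of the 11 genes in the steroid list, 4 were also in another list. For lists with at least 3 measured genes, the median log2 ratio was placed among 10000 random lists of the same size matched on mean CPM, as a description of these libraries.

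Genes named by rule were the 20 with the highest mean CPM, up to 4 members per list with the highest mean CPM, and up to 4 members of each of the 5 most abundant clusters. The rule also took the 5 largest positive and 5 largest negative log2 ratios among genes with a mean of at least 100 CPM and an adjusted p below 0.05. Other genes named were chosen after their values were seen. MicroRNA genes on 1 strand less than 10 kb apart formed a cluster.

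The comparison was tested on simulated Poisson counts for all annotated genes, 200 of them changed, of which 325 genes passed the floor. It recovered 94.7% of 38 genes changed 2-fold and 100% of 53 genes changed 4-fold, and called 2 of 234 unchanged genes. The simulated counts held counting error only, so few false calls follow by construction. The real log2 ratios had an SD of 1.01, against at most 0.213 over 1000 Poisson draws without changed genes. Alternative settings were the counts irrespective of strand, totals without the most abundant gene, TMM-scaled CPM, total-count library sizes, DESeq2 1.42.0 size factors and dispersions, copies summed by stem, other floors, pseudocounts and cluster gaps, and each replicate left out. The counts on the opposite strand were not used for levels, lists or clusters, and are given only for genes with no annotated microRNA gene on that strand.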

Results

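MicroRNA abundance was measured in the adrenal gland, which joins a steroid-producing cortex and a catecholamine-producing medulla, of 2 female B6CASTF1/J mice aged 10 days. Replicate 1 held 5278986 reads, of which 2023410 (38.3%) were assigned to annotated microRNA genes. Replicate 2 held 8555429 reads, of which 3208821 (37.5%) were assigned. A single count was thus worth 0.494 CPM in replicate 1 and 0.312 CPM in replicate 2. With 1 group, the design allows levels within the tissue, the spread between the 2 animals, and the behaviour of gene lists and genomic clusters to be described. No condition was compared with another.

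Mir126a, the microRNA of endothelial cells, and Mir378a, hosted by the metabolic coactivator gene Ppargc1b, had the 2 highest mean shares over the animals, although Mir126a ranked 1 in replicate 1 and 4 in replicate 2. Mir126a took 17.8% of counts in replicate 1 (exact 95% interval 17.7 to 17.8%) and 4.79% in replicate 2 (4.77 to 4.82%), a mean of 11.3% ± 9.18 (SD, n = 2). Mir378a took 9.47% and 12.1%, a mean of 10.8% ± 1.84 (SD, n = 2). The next 3 genes by mean share were members of the let-7 family, Mirlet7b (4.67% and 7.60%), Mirlet7g (5.42% and 4.89%) and Mirlet7i (3.27% and 3.68%). Mir143 of smooth muscle stood at 2.75% and 3.37%, and Mir375, a microRNA typical of neuroendocrine cells, at 2.48% and 3.19%.

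Mir126a lies at chromosome 2, positions 26591357 to 26591429 of mm10, in sequence annotated as exonic in at least 1 transcript of Egfl7. Mir378a lies in an intron of Ppargc1b on chromosome 18, positions 61397835 to 61397900, and Mirlet7g in an intron of Wdr82 on chromosome 9, positions 106178840 to 106178927. Mirlet7b lies at positions 85707319 to 85707403 of chromosome 15, within an exon of the noncoding gene Lncppara. Mir375, at chromosome 1, positions 74900658 to 74900721, overlaps no host gene. Mir126a and Mir378a each overlap an annotated microRNA gene on the opposite strand, and their values rest on strand-specific counting. Irrespective of strand, their reads were set aside as ambiguous, leaving 5.94 CPM for Mir126a and 0 for Mir378a.

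By mean share, the ranks from 8 to 20 were held by Mir139, Mir127, Mir23b, Mir10a, Mir322, Mir23a, Mir22, Mir122, Mir26b, Mir335, Mir10b, Mir99a and Mir99b. Several of these were at similar shares in both animals, such as Mir139 (2.54% and 2.92%), Mir127 of the imprinted Dlk1-Dio3 region (2.91% and 2.38%), Mir322 (1.90% and 2.28%) and Mir335 in an intron of the imprinted gene Mest (1.65% and 1.54%). Others differed more widely. Mir22 stood at 3.02% and 0.656%, Mir122, the main hepatocyte microRNA, at 2.67% and 0.928%, and Mir10b, within the Hoxd cluster, at 0.767% and 2.11%. The 20 genes together took 68.8% of counts in replicate 1 and 66.6% in replicate 2. The top 10 of each library took 54.5% and 48.8%, a mean of 51.7% ± 4.03 (SD, n = 2), and 7 genes were in the top 10 of both. Reads with several alignments, 65.2 and 72.6 per 100 assigned reads in replicates 1 and 2, were left out of these shares and ranks. MicroRNAs with near-identical gene copies may therefore rank too low.

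**Figure D1:**
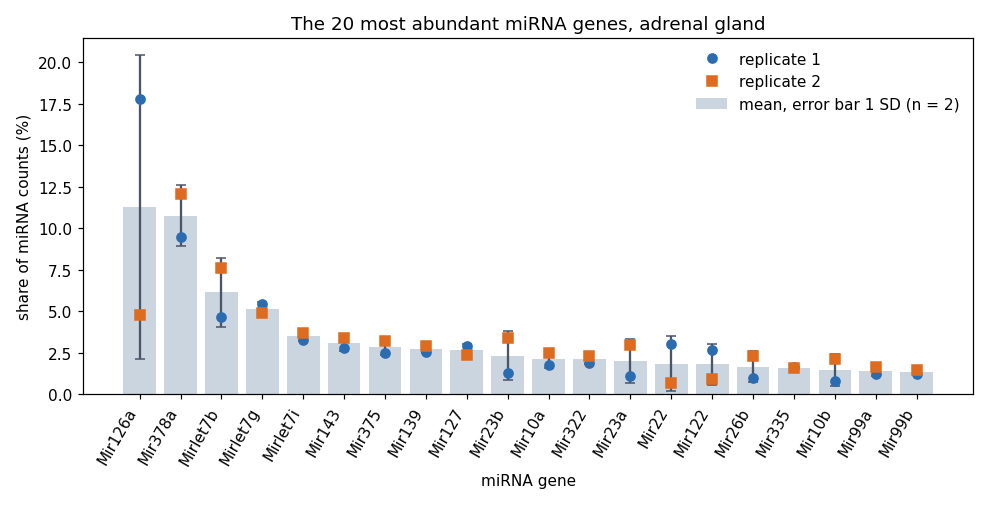
Share of microRNA counts (percent, vertical axis) of the 20 genes with the highest mean share (horizontal axis), with the value of each animal as a point, the mean as a bar and 1 SD (n = 2) as the error bar. Reads with several alignments were not counted. Mir126a has the widest gap, from 4.79% in replicate 2 to 17.8% in replicate 1.

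Of the 2202 annotated microRNA genes, 302 were detected at 10 CPM or more in both animals. At the upper end, 78 genes reached 1000 CPM in both and 18 reached 10000 CPM in both. At least 1 count was seen in both animals for 591 genes and in either for 790. The remaining 1412 had no count in either library. For a gene without near-identical copies this allows up to 1.48 CPM in replicate 1 and 0.935 CPM in replicate 2, and for copies whose reads align to several places it sets no limit.

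Among the families, let-7, which accumulates as tissues differentiate, took 15.5% and 19.04% of counts, with all 12 of its genes at 10 CPM or more in both animals. Genes such as Mirlet7c-1 and Mirlet7c-2 have numbered copies whose shared reads were left uncounted, so this is no total for let-7. The same holds for other lists with numbered copies, among them miR-30, miR-23/27/24 and miR-17/92. The miR-30 family took 2.83% and 3.69%, led by Mir30d (1.23% and 1.39%). The miR-23/27/24 genes took 2.82% and 6.72%, most of it from Mir23a and Mir23b, while Mir24-1 and Mir24-2, which share their mature sequence, were counted at no more than 194 CPM in either animal. The miR-17/92 cluster with its paralogs, linked to proliferation, took 1.54% and 1.86%, with Mir93 at 4399 and 7008 CPM and Mir17 at 4533 and 5876 CPM. The Hox-cluster microRNAs took 2.81% and 5.11%, and the miR-29 family, which represses collagens, 0.193% and 0.0953%. That share is no total for the family, because Mir29b-1 (9.39 and 7.48 CPM) and Mir29b-2 (6.92 and 6.54 CPM) share their mature sequence and lost the reads that align to both. The repetitive family that includes the Sfmbt2 intron cluster took 0.116% and 0.151%, from 7 measured genes among 78.

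The imprinted Dlk1-Dio3 region, whose microRNAs are expressed from the maternal chromosome, took 9.49% and 8.66% of counts, a mean of 9.07% ± 0.584 (SD, n = 2). Of its 59 genes, 48 were at 10 CPM or more in both animals, led by Mir127, Mir411 (9446 and 8198 CPM), Mir379 (7358 and 7144 CPM) and Mir541 (6535 and 6242 CPM). Mir483, in an intron of the imprinted growth factor gene Igf2, stood at 3068 and 1173 CPM. Mir675, in an exon of H19, stood at 28.2 and 22.4 CPM. The 2 genes together took 0.310% and 0.120% of counts.

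MicroRNAs that earlier work tied to adrenal steroid synthesis took 2.55% and 4.04%, led by Mir10b, Mir21a (4685 and 12350 CPM), Mir125a (7747 and 4239 CPM) and Mir214 (3057 and 914 CPM). All 11 genes of that list were at 10 CPM or more in both animals. Mir24-1 and Mir24-2 of that list lost the reads they share, as did its numbered copies of Mir125b, so its share is no total either. Such genes may also rank too low within the list. Neuroendocrine microRNAs took 2.98% and 3.60%, mostly Mir375, with Mir7b at 2333 and 2081 CPM and Mir137 at 869 and 774 CPM. Neuronal microRNAs took 0.0760% and 0.0768%, with Mir138-1 at 384 and 355 CPM. The 6 measured genes of that list all have numbered copies, and the copies of Mir124a and Mir9 were counted at no more than 0.494 CPM each, so the share gives no total for neuronal microRNAs.

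The endothelial list took 17.8% and 4.79%, all but a few counts from Mir126a. The brown fat list took 9.96% and 12.6%, mostly Mir378a, and its other members included Mir455 (3544 and 3815 CPM) and Mir193b (925 and 918 CPM). Smooth muscle and stromal microRNAs took 3.21% and 4.64%, led by Mir143. Leukocyte microRNAs took 0.336% and 0.591%, with Mir342 at 967 and 1857 CPM and Mir142 at 471 and 1023 CPM. Red blood cell microRNAs took 0.0653% and 0.0320%, with Mir451a at 348 and 229 CPM. These shares rest on strand-specific counting where a gene overlaps another on the opposite strand, and irrespective of strand the mean share was 0.0216% for red blood cells, 0.696% for brown fat and 0.0006% for endothelium. Epithelial microRNAs took 0.0742% and 0.327%.

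MicroRNAs of other organs were also counted. Mir122 of the liver has been given above. Striated muscle microRNAs took 1.13% and 0.451%, of which Mir206 was counted at 11177 and 4480 CPM. The numbered copies of Mir1a and Mir133a, main microRNAs of that tissue, were counted at no more than 2.97 CPM each, and because reads fitting several copies were left uncounted this share gives no total for muscle microRNAs. Kidney or gut epithelial microRNAs took 0.0412% and 0.0215%. Mir202 of the gonads stood at 81.5 and 32.7 CPM. The list of pluripotent cells summed to 129 and 189 CPM, that of testis to 13.3 and 16.2 CPM, and that of pancreas to 2.47 and 4.05 CPM, with no pancreas gene at 10 CPM. In total, 11 of the 25 lists took at least 1% of counts in both animals.

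**Figure D2:**
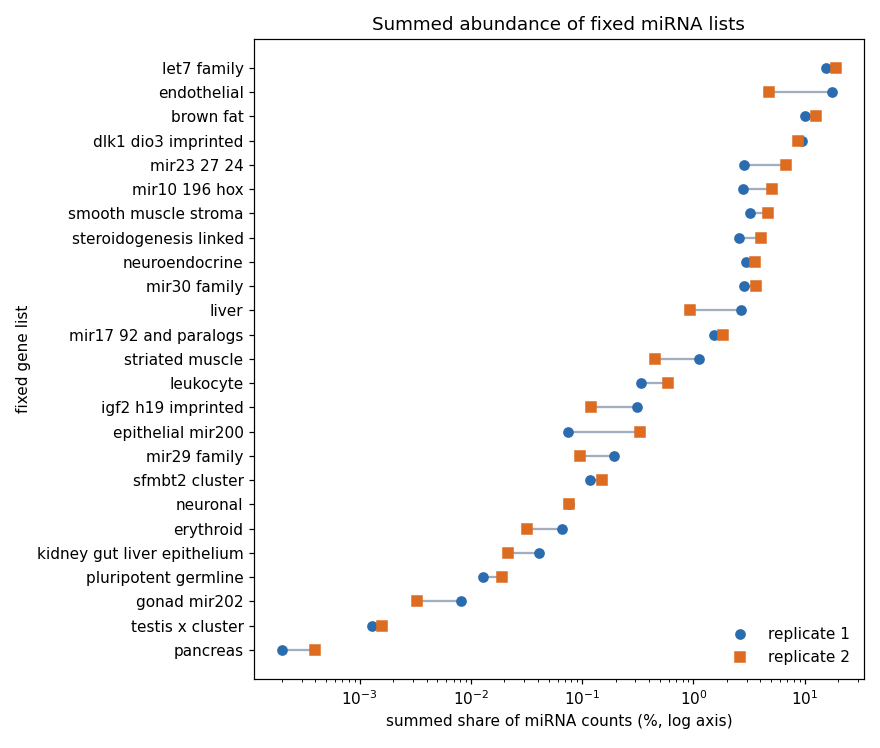
Summed share of microRNA counts (percent, log axis) of each of the 25 gene lists fixed beforehand, with 1 point per animal and a line joining the 2 animals. The let-7 family (15.5% and 19.04%) and the Dlk1-Dio3 region (9.49% and 8.66%) are high in both animals, and the endothelial list spans 4.79% to 17.8%.

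Between the 2 libraries, individual microRNAs differed by more than counting error in both directions. Mir140, known from cartilage, had the largest log2 ratio in favour of replicate 2 among genes with a mean of at least 100 CPM, at 527 CPM in replicate 1 and 6072 CPM in replicate 2 (log2 ratio 3.57, exact 95% interval 3.49 to 3.67). Mir203 of epithelium (300.0 and 2141 CPM, log2 ratio 2.88), Mir145a of smooth muscle (897 and 5579 CPM, 2.68), Mir487b of the Dlk1-Dio3 region (1109 and 6585 CPM, 2.62) and Mir429 of the miR-200 family (46.5 and 275 CPM, 2.59) followed. At the other end of these genes, Mir195a stood at 5135 CPM in replicate 1 and 525 CPM in replicate 2 (log2 ratio -3.24, exact 95% interval -3.32 to -3.17). Mir301 (1218 and 129 CPM, log2 ratio -3.18), Mir340 (229 and 37.7 CPM, -2.52), Mir22 (30246 and 6556 CPM, -2.16) and Mir381 (3099 and 693 CPM, -2.11) were also lower in replicate 2.

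Across the 329 genes measured, Pearson's r of log2(CPM + 1) between the animals was 0.951 (bootstrap interval over genes 0.938 to 0.961) and Spearman's rho was 0.953. Genes are not independent replicates, and no p was attached. Of these genes, 256 (77.8%) differed by less than 1 log2 unit. By the exact conditional binomial test with Benjamini-Hochberg adjustment, 244 genes differed between the libraries, 124 higher and 120 lower in replicate 2. Of these, 73 differed by at least 1 log2 unit, 36 higher and 37 lower. TMM scaling centres the log2 ratios (median -0.0052), so a near-even split is largely built in. The SD of the log2 ratios was 1.01 over all measured genes and 1.15 over the 100 genes with at least 1000 CPM in either animal. The biological coefficient of variation by edgeR was 45.4% (bootstrap interval 41.4 to 49.6%), whereas the median of DESeq2's gene-wise dispersions, a different summary, gave a coefficient of 0.233. The exact test sets these libraries against counting error alone, which separate libraries commonly exceed, and with 1 library per animal, differences between animals and between library preparations are not separated.

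**Figure D3:**
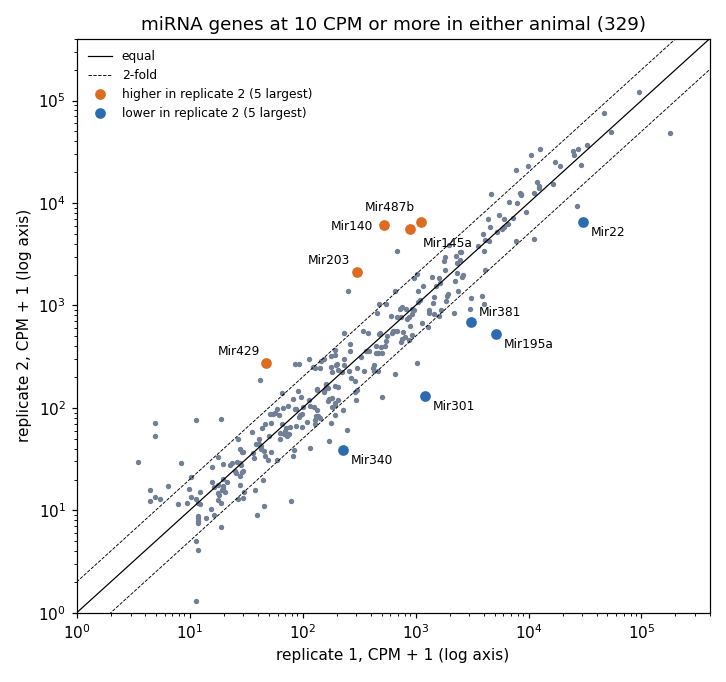
CPM + 1 in replicate 1 (horizontal, log axis) against replicate 2 (vertical, log axis) for the 329 genes with at least 10 CPM in either animal, with equal values on the solid line and 2-fold differences on the dashed lines. Coloured points are the 5 largest differences in each direction among genes with a mean of at least 100 CPM, from Mir140 (log2 ratio 3.57) to Mir195a (log2 ratio -3.24).

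Several gene lists moved together between the animals. All 7 measured epithelial microRNAs were higher in replicate 2 (median log2 ratio 1.43), with Mir200b at 114 and 299 CPM and Mir205 at 128 and 246 CPM beside Mir203 and Mir429. Only 5 of the 7 reached 10 CPM in both animals. The others passed the floor through replicate 2 alone, which fixed their direction. Of 9 leukocyte genes, 7 were higher and 2 lower (median 0.94), including Mir142 (log2 ratio 1.16) and Mir342 (0.99) among the higher. Both lower genes (-2.01 and -0.21) and the gene at the median were numbered copies of Mir181a or Mir181b, whose values are uncertain. Of 5 Hox-cluster genes, 4 were higher and 1 lower (median 1.51), with Mir196b at 679 and 3410 CPM and Mir615 in the opposite direction at 2365 and 1387 CPM. Of 12 let-7 genes, 11 were higher and 1, Mirlet7g, lower (median 0.51), and of 7 Sfmbt2-family genes, 6 were higher and 1, Mir467d, lower (median 1.00).

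Other lists were lower in replicate 2. All 4 measured striated muscle genes were lower (median log2 ratio -1.74), with Mir206 at a log2 ratio of -1.27 and Mir499 at 78.1 and 11.2 CPM. Only 2 of the 4 reached 10 CPM in both animals. Mir133b (17.8 and 5.92 CPM) and Mir208b (38.5 and 8.10 CPM) passed the floor through replicate 1 alone, which fixed their direction. Of 3 kidney or gut epithelial genes, Mir192 (172 and 47.1 CPM) and Mir194-2 (178 and 69.8 CPM) were lower and Mir204 (57.8 and 96.3 CPM) was higher (median -1.29). Of 50 Dlk1-Dio3 genes, 31 were lower, 12 higher and 7 did not pass the test (median -0.34). These 8 lists, 5 higher and 3 lower, lay outside the central 95% of random lists matched on abundance, among the 18 lists with at least 3 measured genes. The let-7 list lay barely outside it (median 0.5099 against an upper bound of 0.5067). Random lists were drawn irrespective of clusters, so their range may be too narrow for lists of clustered genes, such as Dlk1-Dio3. At a floor of 100 CPM the Sfmbt2 family fell inside that range (median 0.70), the smooth muscle and stromal list moved outside it (1.51), and the striated muscle and kidney lists had too few genes.

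The remaining lists lay within that range. All 6 miR-30 genes were higher in replicate 2 (median log2 ratio 0.47). Of 6 smooth muscle and stromal genes, 4 were higher and 2 lower (median 0.53), and all 3 red blood cell genes were lower (median -0.89). Neuroendocrine genes split into 1 higher, Mir375 (log2 ratio 0.41), 5 lower and 4 that did not pass (median -0.34). Steroid-linked genes split into 4 higher, 5 lower and 2 not passing (median -0.11), with Mir21a (1.45) higher and Mir214 (-1.69) lower. Of 6 miR-23/27/24 genes, 2 were higher and 4 lower (median -0.16), and the miR-17/92 genes split into 5 higher, 5 lower and 2 not passing (median -0.19). Of 6 neuronal genes, 1 was higher, Mir128-1 (0.63), and 5 did not pass (median 0.07). Brown fat genes included 3 higher and 3 not passing (median 0.17), and pluripotent-cell genes 2 higher and 3 not passing (median 0.36).

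Lists with fewer than 3 measured genes had no random lists. Both measured miR-29 genes were lower in replicate 2, Mir29a and Mir29c each with a log2 ratio of -0.97. Mir122 (-1.48), Mir126a (-1.84), Mir202 (-1.24) and Mir483 (-1.34) were lower, Mir675 did not pass (-0.27), and Mir547 was the 1 testis gene measured and was higher (1.48). Mir547 passed the floor through replicate 2 alone (3.95 and 12.5 CPM). Counts of genes passing were identical when adjusted over the list alone, except for the neuroendocrine list, where 5 genes passed in place of 6.

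MicroRNAs made from 1 genomic cluster often share a primary transcript. The most abundant of the 124 clusters was Mirlet7b with Mirlet7c-2 on chromosome 15, positions 85706603 to 85707403, with 4.73% and 7.68% of counts. In the Dlk1-Dio3 region of chromosome 12, the 39 genes from 109709060 to 109747960 took 4.55% and 4.50%, and the 14 genes from 109563692 to 109595388, among them Mir127, Mir431, Mir433 and Mir337, took 4.68% and 3.94%. Mir143 with Mir145a on chromosome 18, positions 61647825 to 61649258, took 2.84% and 3.93%. The X-linked cluster of Mir322, Mir351, Mir542 and Mir503, positions 53047997 to 53054349, took 2.75% and 3.05%.

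Members of a cluster could differ widely between the animals even where the summed share was steady. In the 39-gene cluster, log2 ratios ran from -3.09 to 2.62, with Mir487b higher in replicate 2 and its near neighbour Mir381 lower, while Mir379 (0.01) and Mir541 (-0.02) did not pass the test. Mir145a had a log2 ratio of 2.68 beside 0.34 for Mir143, and Mir23a 1.52 beside -0.14 for Mir27a. Mir322 (0.31) was higher and Mir503 (-0.86) lower. Over 157 genes in 44 clusters, the SD of log2 ratios within clusters was 0.89, which is 82.8% of the SD of 1.07 over the same genes.

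**Figure D4:**
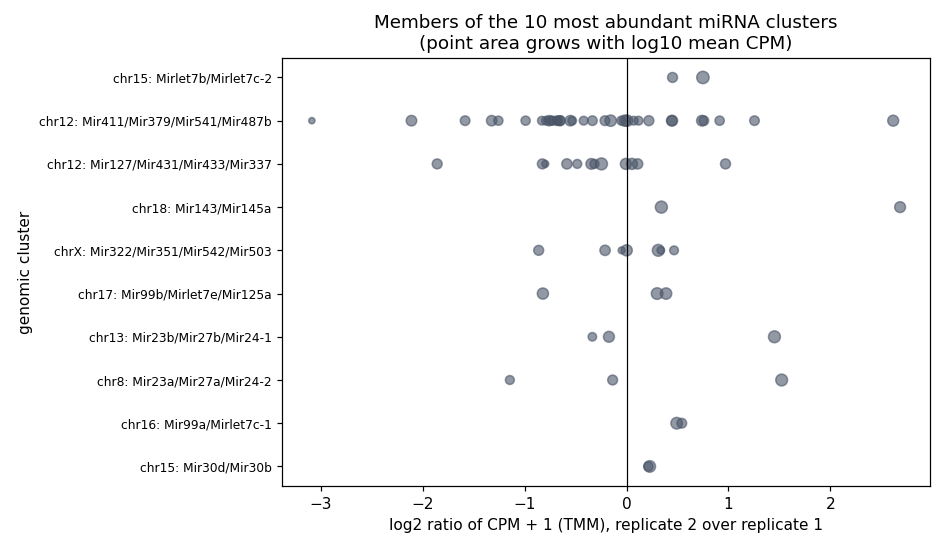
Log2 ratio of replicate 2 over replicate 1 (horizontal axis, TMM-scaled CPM + 1) for measured members of the 10 most abundant microRNA clusters (vertical axis), with 1 point per gene and larger points for more abundant genes. The 39-gene cluster of chromosome 12 spans -3.09 to 2.62, and Mir143 and Mir145a lie at 0.34 and 2.68.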

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

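The tests below of sequence-dependent recovery, cell makeup, foreign tissue and shared reads were chosen after the results were seen, and the test of hairpin GC content was written before its result was seen. Reads on the opposite strand of a gene with no annotated partner there were looked at because they lie outside the main measurement and exceed what a count of 0 allows. Mir203 had such reads at a mean of 40.5 CPM (82 reads in replicate 1 and 130 in replicate 2), equal to 40.5 CPM in each animal, while its own strand held 607 and 6869 reads. Mir7654 had a mean of 2.91 CPM on the opposite strand, from 8 and 6 reads, while its own strand held 8 and 0 reads.

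Some microRNAs from 1 cluster shifted apart between the animals. Several genes of the same number at separate loci shifted alike, such as Mir23a and Mir23b, Mir27a and Mir27b or Mir29a and Mir29c. Others lay far apart, such as those numbered 301, 34 and 26, with mean absolute differences in log2 ratio of 2.95, 1.71 and 1.71. Hairpin GC content accounted for 0.305% of the variance of log2 ratios, which argues against a linear trend with hairpin GC as the main cause. The GC content of the mature sequence was not tested. Within clusters the mean absolute difference in log2 ratio was 0.851 (95% bootstrap interval over clusters 0.635 to 1.08). That lay above the bound of 0.5 chosen for members that shift alike, as did 1.00 (0.770 to 1.26) at a floor of 100 CPM. The bound was set after cluster members had been seen to shift apart, so a mean above it was likely beforehand. It was exceeded in 24 of 35 clusters, and in 20 of 24 at 100 CPM. The comparison therefore cannot decide whether cell makeup or transcription was the sole cause, and a contribution stays open. Cluster members were closer than shuffled ratios at 10 CPM (median 1.07, permutation p = 0.0350). They were not clearly closer at 100 CPM (median 1.06, permutation p = 0.352) or without numbered copies (median 1.07, permutation p = 0.191). Across 27 same-number groups the mean was 0.741 against a median of 1.06 for shuffled ratios (permutation p = 0.0091). The numbers 15, 23, 27 and 29 had prompted that test, and without them it was 0.852 against 1.05 (permutation p = 0.0993). Without them, clusters stood at 0.809 against 1.05 (permutation p = 0.0250). With them, the same-number mean was 0.569 at 100 CPM (permutation p = 0.0013) and 0.654 without numbered copies (permutation p = 0.0061). Cluster minus same-number means gave 0.110 (interval -0.241 to 0.443), and 0.432 (0.0067 to 0.794) at 100 CPM. Without those numbers the difference was -0.0426 (-0.41 to 0.32), so clusters and same-number groups were not clearly told apart. Recovery that depends on the mature sequence, in ligation or amplification, may or may not contribute, and reads passing between near-identical paralogs, shared regulation of paralogs and a difference between the animals in processing of the primary transcripts were not tested.

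MicroRNAs of liver, striated muscle and kidney or gut epithelium were lower together in replicate 2. Over the 8 measured genes of these 3 lists the median log2 ratio was -1.44, against a central 95% of -0.40 to 0.61 for matched random lists, and 7 of 8 were lower. Among the lower genes, Mir133b (17.8 and 5.92 CPM) and Mir208b (38.5 and 8.10 CPM) passed the floor through replicate 1 alone, which fixed their direction. A smaller share of RNA or reads from neighbouring or co-sequenced tissue in replicate 2 may account for the joint shift, with Mir122 (26733 and 9284 CPM) and Mir206 (11177 and 4480 CPM) as its most abundant genes. The question stays open because the 3 lists were picked for showing the pattern, Mir204 moved the other way (log2 ratio 0.77), and the adrenal gland's own level of these microRNAs is not known from 2 libraries. A difference between the animals was not tested.

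Genes with a numbered copy elsewhere had few counts beside their single-copy neighbours. In 18 of 19 clusters the copies lay below the neighbours, with a median difference of -4.94 on the log2 scale (exact sign test p = 7.63e-05), for example Mir24-1 beside Mir23b and Mir27b (-6.91) and Mirlet7c-1 beside Mir99a (-4.94). The exception was Mir194-2 beside Mir192 (0.18). Copies of 1 microRNA, such as Mir24-1 and Mir24-2, entered as separate clusters. The clusters were therefore not independent, and the sign test p may be too small. Reads shared between near-identical copies, which fall among the 25.0% and 27.2% of reads left uncounted for having several alignments, may account for these low values. True differences in processing of the primary transcripts were not tested.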

How the results depend on the processing

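Settings added after seeing the data were the pair distances at 100 CPM, without numbered copies or without the numbers 15, 23, 27 and 29, and the cluster spread without the Dlk1-Dio3 region. Among the named genes and lists, no call made in the main setting changed sign in the settings that gave a value. The log2 ratio of Mir379, which did not pass in the main setting, was 0.0376 with DESeq2 size factors and -0.0426 with total-count library sizes. Irrespective of strand, Mir142, Mir292, Mir30e, Mir337, Mir378a, Mir451a and Mir486 fell below the floor and had no ratio, and the other genes past the test were compared only as counts. Detection fell to 194 genes at 100 CPM in both animals, and genes differing by at least 1 log2 unit to 48 at 100 CPM in either, because fewer genes were counted. Irrespective of strand, the top 10 share was 46.1%, because reads of Mir126a and Mir378a became ambiguous. Pearson's r was 0.978 over genes with 1 count in either and 0.920 at 100 CPM, which widen and narrow the range of abundance. The coefficient of variation was 0.233 from the median of DESeq2's gene-wise dispersions, a different summary from edgeR's common dispersion. Genes differing between the libraries numbered 195 to 247 over all settings, against 244. Total-count or DESeq2 library sizes move all genes alike (by 0.05 log2 units for total counts), so the place of a list among random lists holds by construction there and was not tested by them. Calls of genes near equal, among them Mir335, Mir30b, Mir27a, Mir137, Mir379, Mir541, Mir431 and Mir433, depended on the scaling or the strand column. Leaving out either animal moved no level beyond 1 SD, which holds by construction with 2 animals; agreement, differing genes and list shifts had no such value. No paired analysis was possible because there is 1 group. Depth limits statements on genes below 10 CPM, where 1 count is 0.494 or 0.312 CPM.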

Other observations

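By chromosome, the counts were unevenly spread. Chromosome 18, with Mir378a, Mir143 and Mir122, held 15.0% of counts in replicate 1 and 16.9% in replicate 2. Chromosome 2, with Mir126a and Mir10b, held 20.0% and 8.49%, and chromosome 12, with the Dlk1-Dio3 region, 9.68% and 9.11%. The X chromosome held 5.11% and 5.83%, led by Mir322.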
